A study of Glycine max with 24 samples.

How the data were processed

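RNA from total roots was extracted with TRIzol, treated with DNase, purified on a column, labelled with biotin and hybridised to an Affymetrix soybean array, per the labels' protocols. The deposited table holds log2 expression values for 61170 probe sets on 24 arrays, as read from the values themselves. The background correction, normalization and summarisation behind these values are not given in the sources used here. Value distributions were alike within a harvest day and differed between the days: array medians of soybean probe sets were 8.45 to 8.58 at day 10 and 8.32 to 8.45 at day 14. Within a day 9 to 52 probe sets had exactly equal values on 2 arrays, and across days 0 did. Arrays were therefore treated as if the days had been normalized apart, and no further normalization was applied.

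Samples were grouped by their titles into 8 groups of 3. For the Clark sustained arrays other label fields name the condition differently, and the title was followed. The highest correlation between any pair of arrays was 0.9955, and all 24 were counted separately. Replicate numbers were not used to pair arrays, as set in the plan, since no methods text at hand used them so. In a later check, arrays with the same replicate number did not deviate together.

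Of the probe sets, 37641 are for soybean, 15820 for Phytophthora sojae and 7530 for Heterodera glycines. A further 44 for P. sojae ribosomal RNA were left out as well, which the plan had not named. A soybean probe set was tested where it exceeded, on at least 3 arrays, the 95th percentile of that array's P. sojae and H. glycines probe sets, which left 28191. The platform annotation gave 1 gene for 7341 of these, several for 334 and none for 20516, and a gene symbol other than a LOC number for 1352, from 836 genes. Of 9047 annotated probe sets, 8652 had a gene ID found in the reference table of assembly Glycine_max_v4.0 (GCF_000004515.6), which was used for names and for the order of genes only. Symbols follow that annotation, and 0 needed an update. Probe sets with several genes are not named. Probe sets of 1 gene were tested separately; the value given for a gene is that of the probe set the naming rule chose, and other probe sets are mentioned where they differ. Probe sets without a listed gene are described and not named.

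Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 24 arrays, leaving 16 residual degrees of freedom. There were 13 contrasts: iron limitation and recovery in each line, their interactions with line, Clark against IsoClark over all conditions and in each, and day 14 against day 10 with sufficient iron in each line. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast. The fit assumes a like spread in all groups, whereas the sustained groups varied less than others. Contrasts, filter, tests, alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per contrast, up to 12 largest rises and 12 largest falls with a described gene and groups apart, the 2 largest each way without a description, up to 4 called members of each list, and the main iron genes whether called or not. Where nothing was called, the 5 smallest p-values were given.

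Gene lists were tested with camera in limma at a preset correlation of 0.01 and again with the correlation estimated. Of 32 keyword lists fixed before the data were examined, 7 had at least 3 tested probe sets, since the annotation carries few descriptions. A further 30 lists by gene symbol were written after the annotation was seen and before any gene's values were. They include markers of other tissues. VSPA alone made up the keyword list of cotyledon and seed markers, with 6 probe sets, and the symbol list of that name has 15. VSPA is a vegetative storage protein, so a shift of either list need not reflect these tissues. Its 6 probe sets are of 1 gene, with an estimated correlation of 0.908. The preset correlation of 0.01 treats them as nearly independent, which makes its p-values for VSPA too small. Other lists in the text are the symbol lists. For VSPA the mean over its probe sets was compared by an exact permutation of the labels within each line.

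The procedure was tested on simulated data with 200 changed probe sets in each of 20 draws. For limitation in Clark it recovered 27.2%, 77.0% and 95.2% of changes of 0.5, 1 and 2 on the log2 scale, with 6.51% of calls false. For the lines over 4 conditions it recovered 75.1%, 94.4% and 99.4%, with 0.832% false. The real data for limitation in Clark gave only 2 calls, and another split of the same 6 arrays gave 73. With so few calls the adjustment asks for a smaller unadjusted p than with 200 changed probe sets. The simulated shares recovered and false for limitation in Clark thus need not hold for the real contrast. With random lists the list test found the raised list in 20 of 20 draws and called 0 of 580 others. Members of random lists are not correlated as those of real lists are, so this does not test the preset correlation.

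Alternatives were no filter, a stricter filter on the mean over all 24 arrays at the 99th percentile of the means of P. sojae and H. glycines probe sets, quantile normalization of soybean probe sets, a replicate block, a trended and robust variance, no probe sets ending in _x_at or _s_at, a fit of only the groups compared, and leaving out each array in turn. The line markers, and the listing of the unnamed iron probe set on all 24 arrays, were singled out after their values were seen. Array weights, the removal of doubted arrays and contrasts averaged over lines were added after the data were seen. Array weights were first estimated by limma's default method, which did not converge. The gene-by-gene method replaced it after those counts had been seen.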

Results

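Roots of 2 near-isogenic soybean lines were profiled on an Affymetrix soybean expression array. Clark uses iron efficiently and IsoClark is its iron-inefficient counterpart. Plants grew in hydroponic solution with 100 or 50 uM iron nitrate. Roots of sufficient and limited plants were harvested at day 10. On day 12 iron was added, so that plants kept at sufficient iron (sustained) and plants brought back from limitation (recovery) were harvested at day 14. Each of the 8 combinations of line and treatment had 3 arrays, labelled as biological replicates, which makes 24 arrays. Soybean probe sets above the array's background level numbered 25831 to 27102 per array at day 10 and 25563 to 26846 at day 14. The mean correlation of an array with its own group was 0.935 to 0.976 at day 10 and 0.926 to 0.995 at day 14. A log2 change is given with its standard error (SE) and limma's Benjamini-Hochberg adjusted p, and the number of arrays limits the precision of each.

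The first question was which root transcripts differed at day 10 between limited and sufficient iron in the iron-efficient line. In Clark a probe set with no gene listed, called the unnamed iron probe set from here on, rose by 4.21 on the log2 scale (SE 0.39, 18.5-fold, adjusted p = 6.87e-05), from 6.11 ± 0.53 to 10.3 ± 0.60 (SD, n = 3). Another probe set without a listed gene rose by 3.86 (SE 0.51, 14.5-fold, adjusted p = 0.0066). Clark sufficient arrays read at most 6.71 and 5.85 for these in turn, under their background level of 7.16 to 7.21. The exact size of both folds is thus uncertain. The metal transporter gene DMT1 differed by 0.79 (SE 0.25) and did not pass the test (adjusted p = 0.515). Genes of ferritin, the iron storage protein, were not called either, with a change of 0.12 (SE 0.21) for SFERH-3 and -0.51 (SE 0.30) for SFERH-4. Among listed groups, all 15 probe sets of the cotyledon and seed list were higher under limitation, 0 of them called over all probe sets and 3 adjusted over the list alone. That shift passed camera with its preset correlation (adjusted p = 1.54e-08) and held (adjusted p = 0.0124 with an estimated correlation). Its largest changes were those of 6 probe sets of 1 gene, VSPA, a vegetative storage protein. The shift thus need not reflect cotyledon or seed tissue. The 6 VSPA probe sets alone, the list fixed before the data were examined, were all higher (median 2.66, preset adjusted p = 6.97e-08), with 0 called over all probe sets and 5 adjusted over the list alone. The call of that list was lost (adjusted p = 0.148 with an estimated correlation). Flavonoid and isoflavonoid synthesis genes were lower on 39 of 42 probe sets (median -0.31, preset adjusted p = 1.96e-08), 0 called over all probe sets and 6 adjusted over the list alone. That call was lost (adjusted p = 0.357 with an estimated correlation). Green tissue genes were higher on 14 of 16 probe sets (median 0.67, preset adjusted p = 9.47e-09), with 0 called and 8 adjusted over the list alone, and this too was lost (adjusted p = 0.357 with an estimated correlation). Clark limited replicate 1 stood apart in both lists. As list means relative to the day 10 mean of each probe set, green tissue genes were at 0.57 on it and 0.06 and -0.31 on replicates 2 and 3, against -0.56 to -0.44 in sufficient roots. Flavonoid genes were at -0.48 on it and 0.01 and -0.03 on the others, against 0.39, -0.22 and 0.27. The morning clock genes LHY and LCL3 were also high on that array, as given with IsoClark. In all, limma called 2 of 28191 probe sets, both higher, against 2003 at an unadjusted p under 0.05. Over all tested probe sets, 11.4% had groups that did not overlap, where chance gives 10% with 3 arrays against 3. The count was 1 without Clark limited replicate 1 or Clark sufficient replicate 1, and 13 without Clark limited replicate 3, and 0 with only the groups compared.

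In IsoClark, limitation raised the unnamed iron probe set by 3.71 (SE 0.39, 13.1-fold, adjusted p = 0.000505). LOC100781868 rose by 3.22 (SE 0.42, 9.34-fold, adjusted p = 0.00309) and LOC100785186 by 2.33 (SE 0.44, adjusted p = 0.0466). Sufficient IsoClark arrays read at most 7.05, 6.30 and 7.20 for these probe sets in turn, under their background level of 7.28 to 7.30. The exact size of these changes is thus uncertain. ELIP, an early light-inducible protein of plastids, rose by 1.44 (SE 0.23, adjusted p = 0.0166) and the MYB factor gene MYB138 by 1.01 (adjusted p = 0.047), while a second probe set of MYB138 differed by 1.07 and was not called (adjusted p = 0.136). GASA6, of the gibberellin-regulated peptide family, fell by 1.31 (SE 0.23, adjusted p = 0.039). DMT1 differed by 0.53 (SE 0.25, adjusted p = 0.489). Green tissue genes were higher on 15 of 16 probe sets, 1 called as a rise (ELIP), 15 not called, and 6 called adjusted over the list alone. Their preset adjusted p was 7.21e-09, and the call was lost (adjusted p = 0.357 with an estimated correlation). Circadian clock genes had a median change of 1.57 over 6 probe sets, 0 of them called over all probe sets and 4 adjusted over the list alone (preset adjusted p = 0.00218). That call was lost as well (adjusted p = 0.357 with an estimated correlation). LCL3, a morning clock gene, differed by 1.96 (adjusted p = 0.0906) and LUXC, an evening clock gene, by -0.63 (adjusted p = 0.481). The morning genes LHY and LCL3 averaged 10.3 and 10.2 on IsoClark limited replicates 1 and 2 and 9.15 on Clark limited replicate 1, against 7.56 to 8.32 on the other arrays of day 10. Ferritin probe sets were higher on 6 of 7, with 0 called (preset adjusted p = 0.0222, and adjusted p = 0.551 with an estimated correlation). They were high on the arrays with high clock genes: as list means relative to day 10 they were at 0.55 and 1.20 on IsoClark limited replicates 1 and 2 and 0.62 on Clark limited replicate 1, but at -0.61 on IsoClark limited replicate 3, below the sufficient IsoClark arrays (-0.29 to -0.0017). Green tissue genes were at 0.90, 0.79 and 0.02 on the 3 IsoClark limited arrays, against -0.26 to -0.12. In total 23 probe sets rose and 5 fell, against 2836 at an unadjusted p under 0.05. Groups were apart for 13.1% of all tested probe sets (chance gives 10%). The count rested on single arrays: without IsoClark limited replicates 1, 2 and 3 in turn it was 3, 10 and 1599, and without IsoClark sufficient replicates 1, 2 and 3 it was 6, 4 and 3. It was 0 with only the groups compared and 1986 with array weights. Without the 3 limited arrays with high clock genes it was 4, but the IsoClark limited group then held only replicate 3, assumed to vary like the other groups. The unnamed iron probe set then differed by 3.91 (SE 0.58, adjusted p = 0.0364) and LOC100781868 by 2.24 (SE 0.46, adjusted p = 0.205). ELIP differed by 0.75 (SE 0.19, adjusted p = 0.436), MYB138 by 0.39 (SE 0.16) and GASA6 by -0.76 (SE 0.25), and none of these 3 passed.

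**Figure D1:**
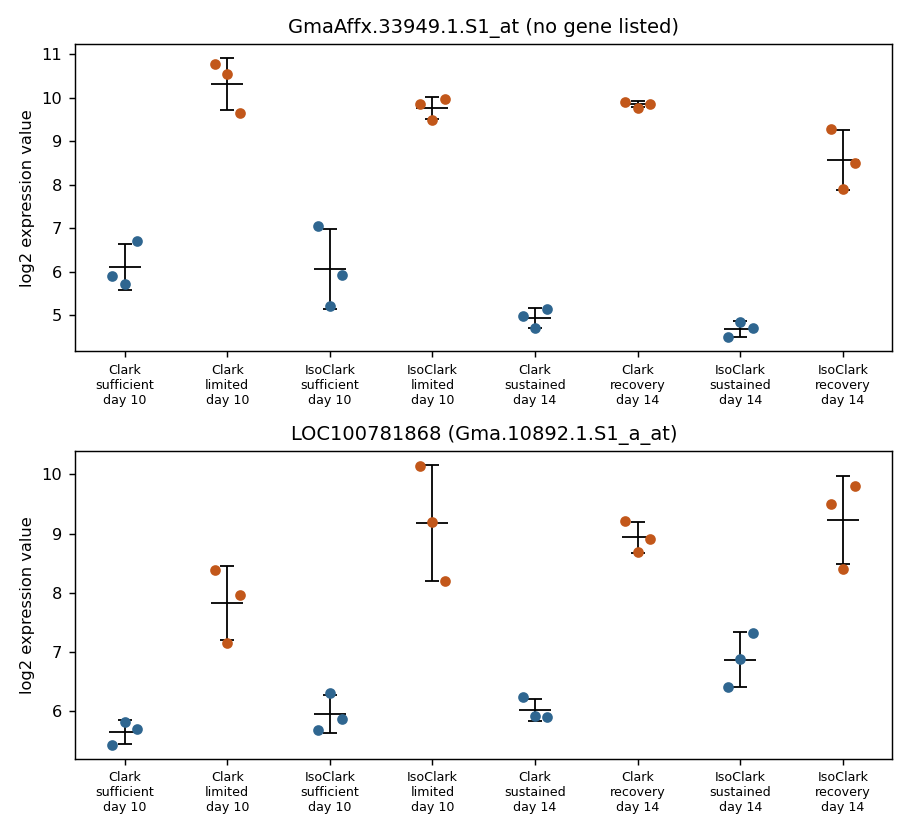
Log2 expression values of the unnamed iron probe set (top) and LOC100781868 (bottom) on each array, by group, with the mean and SD of 3 arrays. The 12 arrays of limited or recovery plants lie between 7.91 and 10.8 for the unnamed iron probe set and the other 12 between 4.49 and 7.05. These other 12 are all under the background level of their arrays.

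**Figure D2:**
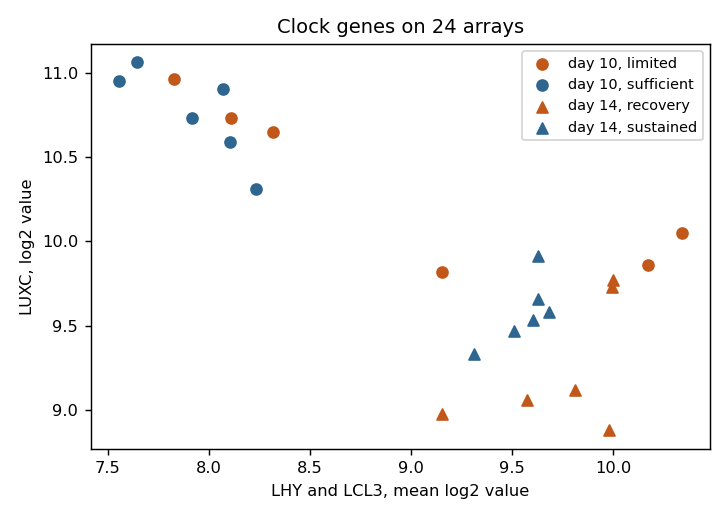
Log2 expression value of the evening clock gene LUXC against the mean of the morning clock genes LHY and LCL3, each point 1 of 24 arrays, by day and iron. At day 10, 3 limited arrays lie at 9.15, 10.2 and 10.3 on the horizontal axis and the other arrays between 7.56 and 8.32.

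Whether the lines differed in their change under limitation was tested as an interaction. The cotyledon and seed list differed between the lines: all 15 probe sets changed more upward in Clark, 3 of them called adjusted over the list alone (preset adjusted p = 2.25e-06, and adjusted p = 0.0373 with an estimated correlation). The 6 VSPA probe sets alone lost their call (preset adjusted p = 7.77e-08, and adjusted p = 0.17 with an estimated correlation), with 4 called adjusted over the list alone. VSPA averaged over its 6 probe sets was 9.74 ± 0.63 in limited and 7.36 ± 0.95 in sufficient Clark roots (SD, n = 3), and 8.08 ± 1.62 and 9.26 ± 1.01 in IsoClark roots. The change was thus 2.38 in Clark and -1.18 in IsoClark, a difference of 3.57. An exact permutation test of no iron effect in either line gave a two-sided p of 0.025 over 400 relabelings, which does not test equal changes. Flavonoid and isoflavonoid synthesis genes changed more downward in Clark on 38 of 42 probe sets (preset adjusted p = 0.000117, and adjusted p = 0.797 with an estimated correlation). GASA6 had the smallest p of any probe set, with a difference of 1.83 (SE 0.33, adjusted p = 0.663). limma called 0 probe sets, against 1865 at an unadjusted p under 0.05. Without IsoClark limited replicate 3 it called 180, so the lines' responses were not shown to be alike.

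The harvest at day 14 asked which differences remained 2 days after iron was restored. In Clark, the unnamed iron probe set was 4.91 higher in recovery than in sustained roots (SE 0.39, 30.1-fold, adjusted p = 5.56e-06), and LOC100781868 was 2.92 higher (SE 0.42, 7.55-fold, adjusted p = 0.0189). Clark sustained arrays read at most 5.14 and 6.24 for these, under their background level of 7.04 to 7.14. The exact size of both folds is thus uncertain. DMT1 differed by 0.27 (adjusted p = 0.623) and SFERH-3 by 0.12 (adjusted p = 0.803). WRKY factor genes, which regulate defence and stress responses, were lower on 70 of 86 probe sets (median -0.32, preset adjusted p = 9.25e-05), with 0 called over all probe sets and 0 adjusted over the list alone. The call was lost (adjusted p = 0.841 with an estimated correlation). NAC factor genes were lower on 23 of 26 probe sets, likewise with 0 called (preset adjusted p = 0.000247, and adjusted p = 0.841 with an estimated correlation). limma called 2 probe sets, both higher, against 3913 at an unadjusted p under 0.05. Groups were apart for 17.6% of all tested probe sets (chance gives 10%). Without Clark recovery replicates 1, 2 and 3 in turn the count was 4185, 1 and 8, and without any of the 3 Clark sustained arrays it was 1. Array weights gave 5956.

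In IsoClark, the unnamed iron probe set was 3.88 higher in recovery than in sustained roots (SE 0.39, 14.7-fold, adjusted p = 0.00025). IsoClark sustained arrays read at most 4.85 for it, under their background level of 7.03 to 7.18, so the exact size of this fold is uncertain. The other 4 called probe sets have no listed gene: 1 rose by 0.75 (adjusted p = 0.0394), 1 fell by 1.94 (adjusted p = 0.0251), 1 fell by 1.49 and 1 fell by 0.92 (both adjusted p = 0.0368). Those that rose by 0.75 and fell by 1.49 and 0.92 were also under the background level in their lower group. Jasmonate and lipoxygenase genes were lower on 26 of 30 probe sets (median -0.25), with 0 called over all probe sets and 3 adjusted over the list alone (preset adjusted p = 4.4e-05, and adjusted p = 0.201 with an estimated correlation). VSPA was 7.89 ± 0.76 in recovery and 11.1 ± 0.27 in sustained roots (SD, n = 3). All 6 of its probe sets were called adjusted over the list alone and 0 over all probe sets. The list's shift passed with the preset correlation (adjusted p = 2.18e-10) and was lost (adjusted p = 0.0741 with an estimated correlation). DMT1 differed by 0.37 (adjusted p = 0.471). The 5 called probe sets, 2 higher and 3 lower, compare with 4451 at an unadjusted p under 0.05. Groups were apart for 30.8% of all tested probe sets (chance gives 10%). Without IsoClark recovery replicates 1, 2 and 3 in turn the count was 2, 1 and 1, and without IsoClark sustained replicates 1, 2 and 3 it was 2, 1 and 56. It was 30 with only the groups compared and 8884 with array weights. It was 0 without both IsoClark sustained replicates 1 and 2, whose line markers are described with the line comparison. The sustained group then held 1 array, assumed to vary like the other groups, and the unnamed iron probe set differed by 3.86 with a larger error (SE 0.59, adjusted p = 0.0842).

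The interaction of line and recovery was called for VSPA as a list of 6 probe sets (preset adjusted p = 8.61e-25, and adjusted p = 0.00224 with an estimated correlation), with all 6 called adjusted over the list alone. VSPA is 1 gene whose probe sets had an estimated correlation of 0.908, so these values do not stand for 6 genes. Its change was 0.97 in Clark, from 8.85 ± 0.69 to 9.82 ± 1.62 (SD, n = 3), and -3.20 in IsoClark, a difference of 4.18. The same permutation test of no iron effect in either line gave a two-sided p of 0.025 over 400 relabelings. The change in IsoClark alone could give such a p. The wider cotyledon and seed list of 15 probe sets, of which VSPA is part, had a median of -0.02 although its test pointed up (preset adjusted p = 1.5e-05, and adjusted p = 0.0642 with an estimated correlation). LOC100804226 had the largest difference among the 5 smallest p-values, 6.26 (SE 1.24, adjusted p = 0.448). It stood at 8.33 ± 2.49 in Clark recovery and 5.71 ± 0.85 in Clark sustained roots, and at 4.55 ± 0.11 and 8.18 ± 1.36 in IsoClark roots (SD, n = 3). limma called 0 probe sets, against 567 at an unadjusted p under 0.05. Without Clark recovery replicate 3 it called 96.

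**Figure D3:**
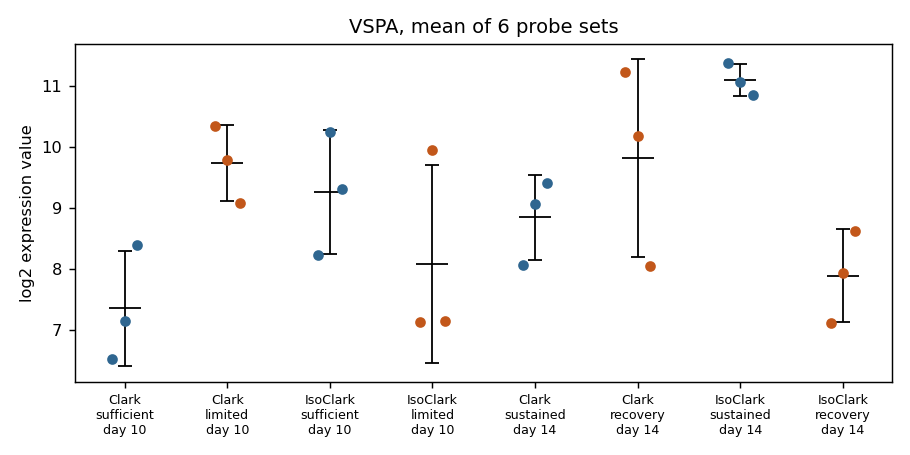
Mean log2 expression value of the 6 VSPA probe sets on each array, by group, with the mean and SD of 3 arrays. Limited roots average 9.74 and sufficient roots 7.36 in Clark, while in IsoClark recovery roots average 7.89 and sustained roots 11.1.

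Fold changes of comparisons that share no arrays were correlated across the 28191 probe sets, which are not independent replicates. Recovery in Clark and in IsoClark gave Pearson's r of 0.47 and Spearman's rho of 0.72, and 78.0% of probe sets changed the same way. Limitation in the 2 lines gave 0.19 and -0.07. Limitation and recovery gave 0.26 and 0.32 in Clark and 0.13 and -0.04 in IsoClark. Leaving out 1 array gave Pearson's r of 0.255 to 0.601 for recovery in both lines and 0.00542 to 0.261 for limitation in both. Of 100 splits of the arrays, 11 gave as large a correlation for recovery in both lines, and more did for the other pairs. Chance is thus not excluded for these correlations. The unnamed iron probe set was called in all 4 iron comparisons when all groups were fitted together. With only the groups compared it was called in recovery, but not under limitation in Clark (4.21, SE 0.38, adjusted p = 0.356) or IsoClark (3.71, SE 0.44, adjusted p = 0.407), where the residual and prior degrees of freedom came to 6.11 and 6.35 against 18.4. The stricter filter, set on the mean over all 24 arrays, left it untested, since its mean of 7.54 was under the threshold of 8.05.

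Clark was set against IsoClark over the 4 conditions together. PRX4, a class III peroxidase gene, was higher in Clark by 1.51 on 1 probe set (SE 0.12, 2.85-fold, adjusted p = 1.92e-06), while its 2 other probe sets differed by 0.20 and 0.17 and were not called (adjusted p = 0.0854 and 0.0835). PRX4 stands for the called probe set from here on. Among WRKY factor genes 23 of 86 probe sets were called higher in Clark, 1 was called lower and 62 were not called, and 41 were called adjusted over the list alone. The largest were WRKY46 (2.01, SE 0.55, adjusted p = 0.0342), WRKY56 (1.88) and WRKY43 (1.82). The list's shift had a preset adjusted p of 4.45e-07 and was not called otherwise (adjusted p = 0.573 with an estimated correlation). Of 30 probe sets of the jasmonate and lipoxygenase list 6 were called higher in Clark, among them AOC4 (1.54, SE 0.29, adjusted p = 0.0058), AOS1 (1.03) and AOS2 (1.02), and LOXB1 was called lower (-0.49, adjusted p = 0.0456). The other 23 were not called, 9 were called adjusted over the list alone, and the list was not called (preset adjusted p = 0.454), with a median of -0.01 although its test pointed up. Other genes higher in Clark were DREB1-like (2.01), the plastid desaturase gene FAD7-2 (2.01), ITPK3 (1.96) and the defence regulator PAD4 (1.11 on 1 probe set, and 0.26 on another that was not called). Lower in Clark were DMT1 (-0.69, SE 0.12, adjusted p = 0.00495), the peroxidase gene Ep (-0.99, adjusted p = 0.019), GSTU41 (-0.62 and -0.44 on 2 probe sets, and 0.11 on another that was not called) and ELIP (-0.46). Phenylpropanoid and lignin genes were lower on 19 of 21 probe sets, with 1 called higher, 2 called lower, 18 not called, and 11 called adjusted over the list alone (preset adjusted p = 0.000766, and adjusted p = 0.667 with an estimated correlation). The nodule list had 1 rise among 6 probe sets and 3 adjusted over the list alone, and was not called (preset adjusted p = 0.45).

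Several of these genes varied within groups. WRKY46 stood at 7.17 on Clark limited replicate 1 and 5.77 on Clark sufficient replicate 2, against 10.4 to 11.05 on the other Clark arrays of day 10 and 5.49 to 8.32 on the IsoClark arrays of that day. FAD7-2 stood at 7.73 and 7.76 on the same 2 arrays, against 11.8 to 12.5, DREB1-like at 6.21 and 6.44, against 10.0 to 11.4, and AOC4 at 9.21 and 8.95, against 10.4 to 11.4. The WRKY list as a whole was at -0.22 and -0.31 on these arrays, relative to day 10, against 0.43 to 0.74 on the other Clark arrays. The same 2 arrays stood apart in a measure of RNA quality: the ubiquitin control gave 1.67 and 1.84 more at its 3' than at its 5' probe set, against 0.60 to 1.10 on the other 10 arrays of day 10. The actin control gave 5.17 and 4.82, against 4.72 to 5.07. WRKY46 passed the test in 20 of 34 other settings and FAD7-2 in 11 of 33. Ep stood at 12.8 and 12.2 on IsoClark sustained replicates 1 and 2 and at 8.50 to 10.3 on all other arrays, and without these 2 arrays its difference was -0.52 (adjusted p = 0.0197). The IsoClark sustained group then held 1 array, assumed to vary like the other groups. PRX4 passed (1.67, adjusted p = 2.23e-07). WRKY46 (2.18, adjusted p = 0.074), WRKY43 (2.00, adjusted p = 0.0689), DREB1-like (2.17, adjusted p = 0.0868), FAD7-2 (2.17, adjusted p = 0.0973) and ELIP (-0.48, adjusted p = 0.061) did not, with differences no smaller than over all arrays and larger errors, as for WRKY46 (SE 0.64 against 0.55).

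In all, 1521 probe sets were higher in Clark and 689 lower, of which 1466 and 568 had the same direction in all 4 conditions. Changes of at least 2-fold made up 271 of the higher and 14 of the lower. After quantile normalization 1415 were higher and 1185 lower. The count was 4198 without Clark sufficient replicate 2, 9825 without Clark recovery replicate 1 and 1119 without Clark sufficient replicate 3, and 14 of the 24 arrays moved it by over 1.5 times. Array weights gave 11805.

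Within single conditions fewer passed with all groups fitted together. PRX4 was higher in Clark by 1.73 under limitation (adjusted p = 0.0119), by 1.59 with sufficient iron (adjusted p = 0.0346) and by 1.57 in recovery (adjusted p = 0.0263), and was not called in sustained roots (1.16, adjusted p = 0.108). A probe set with no gene listed was higher by 1.60, 1.55 and 1.80 in those conditions. LOC100785186 was lower in Clark by -2.88 under limitation (adjusted p = 0.0213), and a probe set with no gene listed by -3.24 in recovery (adjusted p = 0.0124). In sustained roots 2 probe sets without a listed gene were 0.83 and 0.72 higher in Clark. The counts were 7 higher and 4 lower under limitation, 2 higher with sufficient iron, 2 higher in sustained roots, and 2 higher and 1 lower in recovery. Groups were apart for 23.4%, 8.03%, 41.5% and 9.99% of all tested probe sets in that order (chance gives 10%). These counts depended on the variance model. With only the groups compared they were 4 under limitation, 1 with sufficient iron, 4684 in sustained roots and 0 in recovery, and with array weights 3427, 4, 9008 and 1013. After quantile normalization limitation gave 18 higher and 29 lower. Leaving out 1 array gave 0 to 1856 under limitation (highest without IsoClark limited replicate 3), 0 to 125 with sufficient iron (without Clark sufficient replicate 2), 0 to 23 in sustained roots (without Clark sustained replicate 3) and 0 to 4997 in recovery (without Clark recovery replicate 1).

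PRX4 varied within the sustained IsoClark group. On 5 probe sets that separated the lines on the 18 arrays of the other conditions by over 0.3, the median share of the Clark level was 0.968 to 1.13 on the 6 Clark arrays of day 14. It was 0.517 and 0.258 on IsoClark sustained replicates 1 and 2 and -0.0253 on replicate 3. Without replicates 1 and 2 of that group, which leaves it 1 array, the comparison of the lines over 4 conditions gave 884 calls.

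**Figure D4:**
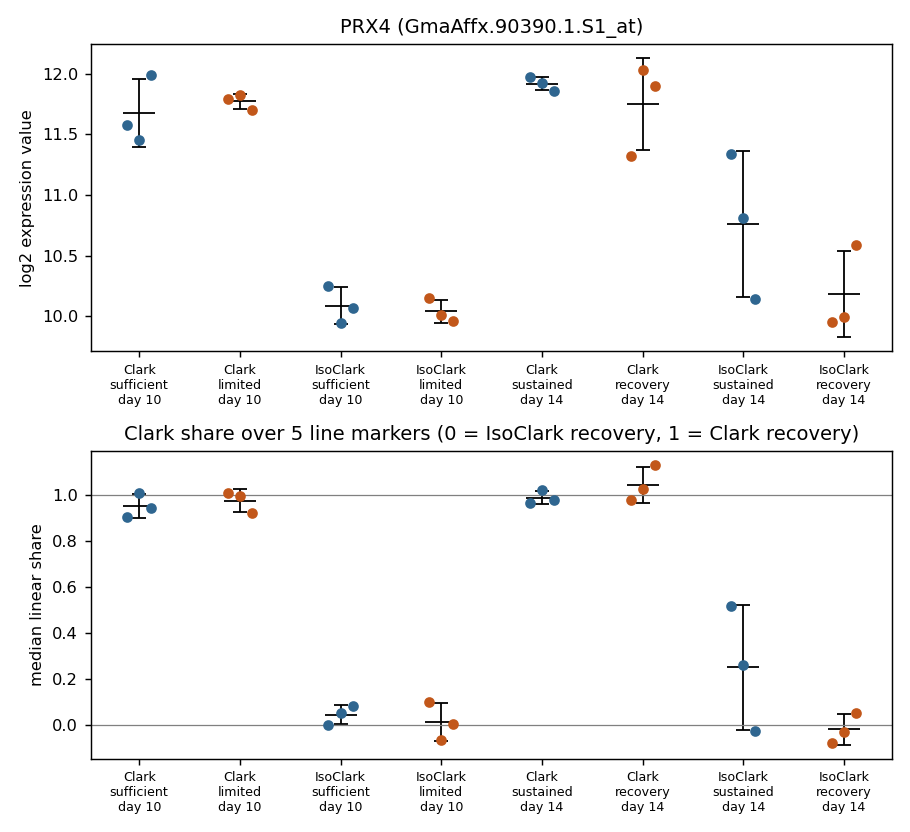
Log2 expression values of PRX4 (top) and the median share of the Clark level over 5 line markers on a linear scale (bottom) on each array, with group mean and SD; 0 is the mean of IsoClark recovery arrays and 1 that of Clark recovery arrays. IsoClark sustained replicates 1 and 2 lie at 0.517 and 0.258.

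Day 14 was set against day 10 with sufficient iron throughout. Iron was also added to the sustained plants on day 12, after the harvest of day 10. Values are given relative to the median change of all probe sets, -0.19 in Clark and -0.16 in IsoClark. The SE, adjusted p, calls and list medians are those of the log2 changes without that subtraction. Photosynthesis genes rose in both lines: the rubisco activase genes RCA14 (3.93 in Clark and 3.53 in IsoClark) and RCAALPHA (3.98 and 3.24), the magnesium chelatase subunit gene CHLH (3.03 and 3.10) and ELIP (2.32 and 2.46). In the green tissue list 11 of 16 probe sets rose in each line and 0 fell, with 11 in Clark and 12 in IsoClark adjusted over the list alone. Their preset adjusted p was 3.5e-19 in Clark (adjusted p = 0.0611 with an estimated correlation) and 7.11e-14 in IsoClark (adjusted p = 0.121 with an estimated correlation). The defence gene PR1-1 rose by 5.51 (SE 1.13, adjusted p = 0.0038) and 4.31 on 1 of its 2 probe sets, and the other rose less, with a log2 change of 1.74 in Clark (adjusted p = 0.0271), and was not called in IsoClark (1.09, adjusted p = 0.127). The morning clock gene LCL3 rose by 2.19 and 2.30, whereas the evening gene LUXC was lower, at -1.06 and -0.94. As an average of LHY and LCL3, sufficient arrays of day 10 were at 7.56 to 8.23 and sustained arrays of day 14 at 9.31 to 9.68. Limited arrays of day 10 with high clock genes, at 9.15 to 10.3, also had high green tissue genes. The hour of harvest was thus not separated from the day for clock and photosynthesis genes. Ferritin genes rose on 2 of 7 probe sets in each line, with SFERH-3 at 1.40 and 1.14, and 5 were not called (preset adjusted p = 0.00113 and 0.00209). That ferritin shift was lost in both lines (adjusted p = 0.23 and adjusted p = 0.281 with an estimated correlation). DMT1 was lower, by -0.58 and -0.63, as were DOF10 (-1.78 and -1.13) and the protease inhibitor gene BBI-2 (-1.33 and -1.30). The MYB list had a median of -0.12 in Clark although its test pointed up (preset adjusted p = 0.0287, and adjusted p = 0.342 with an estimated correlation).

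Between the days 908 probe sets rose and 5015 fell in Clark, and 1235 rose and 6624 fell in IsoClark. Groups were apart for 46.2% of all tested probe sets in Clark and 56.1% in IsoClark (chance gives 10%). After quantile normalization 1191 rose and 1132 fell in Clark, and 1507 rose and 3483 fell in IsoClark. Of the 23350 probe sets for Phytophthora sojae and Heterodera glycines, organisms whose probe sets the array also carries, 43.6% were called between the days in Clark (4403 higher and 5772 lower) and 51.3% in IsoClark (3873 higher and 8113 lower). For soybean probe sets array weights gave 9604 and 16363 calls, no filter 10245 and 12680, and a fit of only the groups compared 11911 in IsoClark. The count in Clark was 2735 without Clark sufficient replicate 2, 3302 without Clark sustained replicate 1 and 3156 without Clark sustained replicate 3. That in IsoClark was 5103 without IsoClark sufficient replicate 1, 4770 and 4023 without IsoClark sustained replicates 1 and 2 in turn, and 364 without both, which leaves 1 sustained array, assumed to vary like the other groups. ELIP, RCA14 and CHLH then passed. The log2 changes of those that did not, not taken relative to the median, were 4.69 for PR1-1 (SE 1.68, adjusted p = 0.163, against 4.15, SE 1.13, over all arrays), 3.17 for RCAALPHA (against 3.08), 2.14 for LCL3 (against 2.14), -1.23 for LUXC (against -1.10), 0.90 for SFERH-3 (against 0.99) and -0.57 for DMT1 (against -0.79). The error of each was larger than over all arrays. Day, the iron addition on day 12 and the processing of the arrays cannot be told apart in these comparisons.

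**Figure D5:**
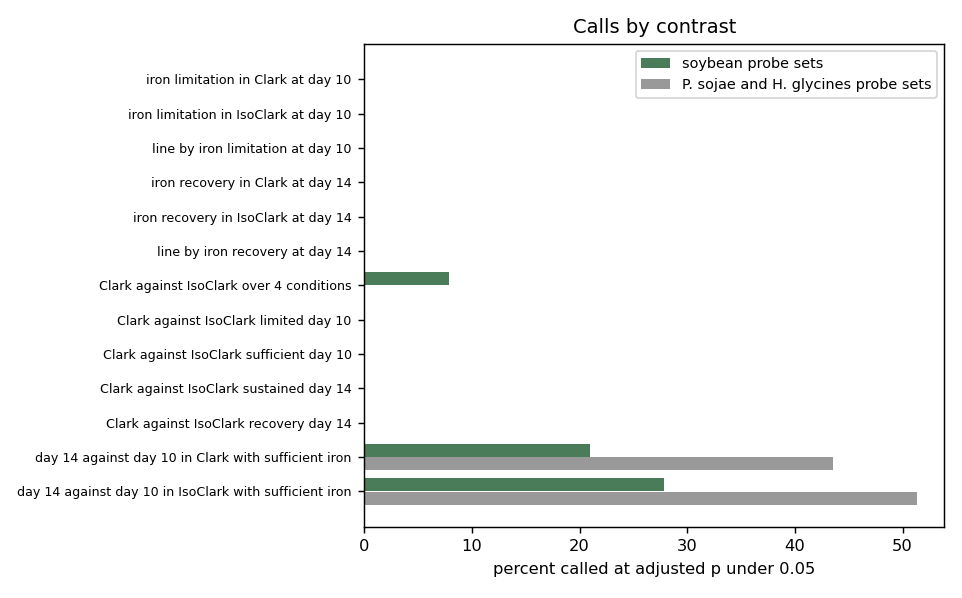
Percent of probe sets called at an adjusted p under 0.05 in each comparison, for 28191 soybean probe sets and 23350 probe sets of P. sojae and H. glycines. Between the days 43.6% (Clark) and 51.3% (IsoClark) of the probe sets of the other organisms were called, a larger share than of soybean probe sets in both lines.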

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

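The choice of the explanations tested here was made only after the patterns were seen, and so were the tests of exchanged labels, shoot tissue and the days. The marker test for RNA of both lines and the test of clock genes had bounds set beforehand, but the bootstrap interval and the values for 10 arrays were added after their results were known. The bounds of the shoot tissue test and of the test of the days were rewritten after their values were seen.

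The cotyledon and seed list differed between the lines in its change under limitation (adjusted p = 0.0373 with an estimated correlation), and the VSPA probe sets differed in their change in recovery (adjusted p = 0.00224 with an estimated correlation). Each time the other of these 2 lists was not called (adjusted p = 0.17 for VSPA under limitation and adjusted p = 0.0642 for the wider list in recovery, with an estimated correlation). The difference in VSPA stayed between 3.07 and 4.50 at day 10, and between 3.47 and 5.06 at day 14, when each array was left out, and was 4.20 and 3.93 without the arrays doubted below. Probe sets of P. sojae and H. glycines, which the comparisons of soybean genes do not use, were called higher in 3 of the 4 comparisons of iron: 1 under limitation in Clark (H. glycines), 12 under limitation in IsoClark (4 P. sojae and 8 H. glycines), and 7 in recovery in Clark (3 and 4). Over 4 conditions 2 were called higher in Clark than in IsoClark, and under limitation 1 was called lower. Between the days more fell than rose (5772 and 4403 in Clark, 8113 and 3873 in IsoClark).

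Line markers lay between the lines on IsoClark sustained replicates 1 and 2. An exchange of Clark and IsoClark labels needs a partner out of place. The 3 Clark sustained arrays, which were not used to choose the markers, had shares of 0.968 to 1.02. This argues against an exchange within the sustained groups. The markers were chosen to separate the lines on all other arrays, so a partner there could not show. RNA or plants of both lines would place further markers between the lines too. On 13 markers not looked at before, the share was 0.382 on replicate 1 (bootstrap 95% interval 0.0856 to 0.766) and 0.00842 on replicate 2 (-0.111 to 0.190). The second value is under the bound of 0.15 set beforehand, yet its interval passes that bound, so a mixture may still have contributed and cannot be told apart from the spread of these markers.

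Clock and green tissue genes were high on 3 limited arrays of day 10, IsoClark replicates 1 and 2 and Clark replicate 1. A harvest at another hour of the day may account for this and would set morning against evening clock genes. An effect of iron on the clock could do so too, so their relation cannot decide between these explanations. Over the 12 arrays of day 10 the morning genes LHY and LCL3 ran against the evening gene LUXC (Pearson r = -0.875, permutation p = 0.00056, and Spearman rho = -0.888, permutation p = 0.00024). The 2 highest arrays lay apart. The other 10, among them Clark limited replicate 1, gave r = -0.923 (exact p = 0.000523) and rho = -0.855 (exact p = 0.00286). Within groups r was -0.864, and at day 14 it was 0.265. Shoot tissue in the harvest stays open, since at least 14 of 16 green tissue probe sets were higher in each line, which is the pattern itself, and the leaf gene CAB3 differed less (medians 0.67 and 0.44) than RCA14 (1.31 and 1.90) from a high level of 11.4. An effect of iron on these genes was not separated from the hour.

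Many more probe sets fell than rose between the days. At least 43.6% of the probe sets of organisms not under study were called too, but with 1.31 falls per rise in Clark and 2.09 in IsoClark, against 5.52 and 5.36 for soybean probe sets. Separate normalization or hybridisation of the days may thus have contributed to the calls, and whether it gave the excess of falls stays open. Growth of the plants over 4 days stays open too, and so does the iron addition on day 12, as the days share no arrays. So does another hour of harvest for the clock and green tissue genes.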

How the results depend on the processing

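Array weights, the removal of doubted arrays and all settings of the averaged contrasts were chosen after the data were seen. Array weights used limma's gene-by-gene method, adopted after the default method did not converge and its counts had been seen. Offsets on the log scale were not run, since the values already are log2. The cause was not tested for any change listed here, except where fewer probe sets or arrays entered by construction. Signal over background limits which probe sets were tested.

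Leaving out 1 array gave 1 to 13 calls for limitation in Clark, 3 to 1599 in IsoClark and 0 to 180 for their interaction; 1 to 4185 for recovery in Clark, 1 to 56 in IsoClark and 0 to 96 for the interaction. Clark against IsoClark gave 1119 to 9825 over 4 conditions, 0 to 1856 under limitation, 0 to 125 with sufficient iron, 0 to 23 in sustained roots and 0 to 4997 in recovery. The days gave 2735 to 6195 in Clark and 4023 to 6306 in IsoClark. Averaged limitation, recovery and history gave 26 to 1134, 34 to 8427 and 174 to 4549. Correlations ran from 0.00542 to 0.261 and 0.255 to 0.601 between lines for limitation and recovery, and from -0.0218 to 0.426 in Clark and 0.0390 to 0.208 in IsoClark.

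With no filter, Clark against IsoClark gave 36 under limitation and 7 in sustained roots, and the days 10245 and 12680. With the stricter filter, limitation gave 0 in Clark and 10 in IsoClark, recovery 0 and 1, the lines 2 under limitation and 1 in sustained roots, and the days in Clark 3554. Quantile normalization gave 5 for limitation in Clark, 2 for recovery in IsoClark, 47 and 1 for the lines under limitation and in sustained roots, and 2323 and 4990 for the days. Fitting only the groups compared gave 0 and 0 for limitation in Clark and IsoClark, 30 for recovery in IsoClark, 4, 1, 4684 and 0 for the lines under limitation, with sufficient iron, in sustained roots and in recovery, 11911 for the days in IsoClark, and 7 for averaged limitation. Without probe sets ending in _x_at or _s_at averaged limitation gave 54.

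The replicate block gave 8 calls for limitation in Clark and 3, 0 and 8 for the lines under limitation, with sufficient iron and in sustained roots, and changed no other count by over 1.5 times. Of 36 pairs of same-numbered arrays from different groups of a day, 16 correlated over 0.1 (range -0.694 to 0.686), and 9 of 24 arrays correlated best with their own number.

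Array weights gave 1986 for limitation in IsoClark, 4 for its interaction, 5956 and 8884 for recovery in Clark and IsoClark, and 11805, 3427, 4, 9008 and 1013 for the lines over 4 conditions, under limitation, with sufficient iron, in sustained roots and in recovery. The days gave 9604 and 16363, and the averages 783, 13135 and 5947. Leaving out the doubted arrays leaves 1 group with 1 array, assumed to vary like the other groups, so fewer calls follow in part by construction. Without the 2 IsoClark sustained arrays, recovery in IsoClark gave 0, the lines over 4 conditions 884, the days in IsoClark 364, averaged recovery 4 and history 41, and the correlation of limitation and recovery in IsoClark was -0.0338. Without the 3 limited arrays, limitation in IsoClark gave 4, the lines under limitation 0, averaged limitation 31 and history 103. With an estimated correlation 2 of 390 list tests were called, against 94 with the preset correlation. The naming rule gave 255 called results, each a probe set in 1 comparison, some without a listed gene. Of these, 203 to 254 were still called in settings that used them all. The lowest share on leaving out 1 array was 34 of 61, without Clark recovery replicate 2. Smaller shares than in the settings with all results were called without the doubted arrays, which leaves 1 group with 1 array. Ep alone changed sign, from 1.66 to -0.22 in the days in IsoClark without the 2 IsoClark sustained arrays.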

Other observations

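The contrasts averaged over lines, the neighbour test and the splits of all comparisons other than the correlations were chosen only after the data were seen.

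Averaged over both lines, limitation at day 10 raised 71 probe sets and lowered 13. CYP82A3, a cytochrome P450 gene, rose by 2.50 (SE 0.49), the glutathione S-transferase gene GSTU37 by 1.66 (SE 0.22, adjusted p = 0.00174), RCA14 by 1.56 (SE 0.32), the peptide gene PSK3 by 0.93 (SE 0.16) and PETC, a photosynthetic electron transport gene, by 0.87. The lignin pathway gene 4CL fell by 0.33. Without the 3 limited arrays with high clock and green tissue genes the IsoClark limited group held 1 array, assumed to vary like the other groups. GSTU37 then passed (2.05, adjusted p = 0.000331), whereas CYP82A3 (2.54, SE 0.47, adjusted p = 0.0557), PSK3 (0.78), RCA14 (0.56, SE 0.18, adjusted p = 0.586), PETC (0.46) and 4CL (-0.25) did not. In recovery 1335 rose and 499 fell, with PSK3 (0.74), GR (0.35) and the sulfite reductase gene SIR (0.35) among the rises, and Ep (-1.32), the calmodulin gene SCAM-4 (-1.19), PDH (-0.96) and GSTU9 (-0.83) among the falls. Without IsoClark sustained replicates 1 and 2, which leaves 1 array in that group, assumed to vary like the others, none of these 7 genes passed (adjusted p = 0.353 to 0.366). The changes were then 0.66 for PSK3 (SE 0.20 against 0.16), 0.33 for GR, 0.28 for SIR, -0.77 for PDH and -0.85 for GSTU9. These and that of SCAM-4 (SE 0.36 against 0.29) lay within 1.5 times of those over all arrays, with larger errors. Ep differed by 0.04 in Clark and -2.69 in IsoClark, where neither passed, and its average moved from -1.32 (SE 0.34) to -0.39 (SE 0.16) without those 2 arrays.

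Over both lines and both days, a history of low iron raised 262 probe sets and lowered 274. GSTU37 (1.11), PSK3 (0.84), MYB109 (0.71) and DMT1 (0.49, SE 0.12, adjusted p = 0.0488) were higher. The ammonium transporter gene AMT1.3 (-0.79, SE 0.17), the nitrate transporter gene NRT2 (-0.75, SE 0.17), WRKY19 (-0.66) and NAC34 (-0.63) were lower. GSTU37 and PSK3 also passed without the 2 IsoClark sustained arrays and without the 3 limited arrays, each of which leaves 1 group with 1 array. The other 6 genes passed in neither case. Their values without the sustained and without the limited arrays were 0.44 and 0.61 for DMT1, 0.67 and 0.40 for MYB109, -0.82 and -0.45 for AMT1.3, -0.72 and -0.59 for NRT2, -0.68 and -0.56 for WRKY19, and -0.67 and -0.40 for NAC34. Only MYB109, AMT1.3 and NAC34 moved by over 1.5 times, without the limited arrays. These averages depend on single arrays: leaving out 1 gave 26 (IsoClark sufficient replicate 2) to 1134 (IsoClark limited replicate 3) for limitation, 34 (IsoClark sustained replicate 1) to 8427 (Clark recovery replicate 1) for recovery, and 174 to 4549 (the same arrays) for history.

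DNA segments that differ between near-isogenic lines could place line differences in neighbouring genes. Among 5297 genes in the order of Glycine_max_v4.0, 511 of them called, 35 neighbouring pairs were called the same way, against a mean of 27.6 and a highest of 47 in 10000 shuffles (one-sided permutation p = 0.086). This misses the threshold of 0.05 and does not exclude such segments. The bound for counting against them was first a p of 0.05 or more and was moved to 0.5 after the value was seen. PRX4 and LOC100787483, both line markers, have 3 measured genes between them. This pair was singled out from the same data, and whether it lies closer than chance gives was not tested.

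Other splits of the same arrays were counted for each comparison. For the lines over 4 conditions, 1 of 100 splits, the real one, gave as many as 2210 calls (highest other 712), a share under 0.05. Chance is thus unlikely to give that count, but 100 splits in a test chosen after the data were seen do not exclude it. The averaged recovery (1834 calls, 3 of 100 splits, highest other 6895) and the averaged history (536, 3 of 100, highest other 2069) had a share under 0.05 as well. Splits that call several times the real count point to a structure of the samples. For averaged limitation 6 of 100 splits gave as many as 84 (highest other 770), so chance is not excluded. The interactions called 0, so all 100 splits gave as many (highest other 665 for limitation and 5 for recovery). The correlations did not exclude chance: as large a size came from 59 of 100 splits for limitation in both lines (highest other 0.639), 11 for recovery in both lines (0.736), 35 for limitation and recovery in Clark (0.594) and 56 in IsoClark (-0.458).

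Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. Real counts and the highest of the other splits were 2 and 73 for limitation in Clark (as many in 2 splits), 28 and 197 in IsoClark (2), 2 and 4 for recovery in Clark (2), and 5 and 0 in IsoClark (1). For Clark against IsoClark they were 11 and 1551 under limitation (2), 2 and 929 with sufficient iron (2), 2 and 0 in sustained roots (1), and 3 and 3962 in recovery (4). Between the days they were 5923 and 0 in Clark (1) and 7859 and 0 in IsoClark (1). Splits that call several times the real count, as for limitation and for the lines under limitation, with sufficient iron and in recovery, point to a structure of the samples.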
